A study of Mus musculus with 4 samples.

How the data were processed

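RNA was measured in single CD8+ T cells from mouse tumours, in 4 samples with 1 library each. Per the labels, female C57BL/6 mice aged 12 weeks carried tumours of Lewis lung carcinoma cells with inducible cGAS. OT-I cells that express STING (CD45.1/2) and OT-I cells that lack it (CD45.1/1) were transferred together and sorted apart after re-isolation. Per the labels' protocols, tumours were digested with collagenase IV and DNase I, red cells were lysed, and libraries were made with the BD Rhapsody whole transcriptome and Sample Tag protocol. Kits of this type prime on poly(A) tails and so count the 3' ends of transcripts. Groups were taken from the sample titles: STING-expressing or STING-deficient, with cGAS induced or not.

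The deposited values are whole-number counts of unique molecules (UMIs) per gene and cell, with no normalization, per the labels' protocols and the files' integer values. The submitters' processing notes name the genome build mm39. The aligner, the counter, their versions, the annotation and the cell calling are not given in the sources used here, nor is the way Sample Tags were used. Every barcode in the matrices has at least 3166 UMIs, so barcodes with fewer UMIs had been left out before deposit by a step the sources do not describe. The 4 matrices list 20556 genes in all and 18292 genes in common, and a gene must be listed in all 4 to be compared. How reads that match several genes were counted is not given either, so genes that share sequence with a copy elsewhere are less certain.

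Cells were kept with at least 500 genes and at most 20% of UMIs from mitochondrially encoded genes, which removed 332 of 65435 barcodes. The remaining 65103 cells were clustered together with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen after leaving out both interferon lists, the cGAS-STING and dissociation lists, and ribosomal, mitochondrial and receptor segment genes. The neighbour graph used 30 principal components and 15 neighbours, and Leiden clustering was run at resolution 0.8. A cluster was named for a class, as X-like, when at least 3 of the class's fixed markers were among its 50 leading genes by fold and at least 1 among its 10 leading genes, with no other class better represented there. A non-T name also needed a low level of CD8 T cell markers. These thresholds were set after the data had been seen, while the markers had been fixed before. Clusters named macrophage or monocyte-like, neutrophil-like, dendritic cell-like and fibroblast or endothelial-like were left out, which left 61997 cells. Doublets were sought with Scrublet in each library, which called 0, 4, 2 and 0 cells in the order used in the report, too few for the caller to have worked, so no doublets were removed in the values reported.

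UMIs were summed over the kept cells of each library and scaled to CPM of that library's sum (from 162603921 to 201244078 UMIs). Ratios are log2 of CPM plus a pseudocount of 1 CPM in both libraries, and folds are plain ratios of the summed counts per UMI. Exceptions are the folds in left-out myeloid-like cells and the within-cluster induction ratio of Cadps2, which include the pseudocount. Single sums have exact Poisson intervals, folds exact conditional intervals and shares exact Clopper-Pearson intervals, each at 95% and for counting error only (scipy 1.17.1, pandas 2.3.3). List medians have intervals from 1000 Poisson redraws of the counts. With 1 library per group no test, p-value or standard error was computed, and genes were not counted as changed. UMIs count molecules, so amplification does not enter these intervals, but mouse-to-mouse, sort and library variation does not either.

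The 17 gene lists were type I interferon response, interferon gamma response, NF-kB response, integrated stress and unfolded protein response, p53 targets and apoptosis, cell cycle, cytotoxic effector, inhibitory receptors and exhaustion, stem-like and memory, tissue residency, T cell activation, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded, dissociation and heat shock, and cGAS-STING pathway genes. The 16 marker sets covered CD8 T cells, 4 of their states, and other cell types the tumour or the gate could hold. A list was described over members with at least 1 CPM in at least 1 library. Each median was placed among 10000 random lists in which each member was replaced by 1 of the 100 genes nearest in mean expression. A list is given its direction in the report where the median fell outside the central 95% of these, and a gene's ratio was read as having a direction where its counting interval excluded 0 and its size was at least 0.1. Both readings were settled after the data had been seen.

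The lists, the comparisons, the clustering settings, 21 alternatives and the rule for named genes were fixed before the data were examined. That rule takes, in each comparison, the 8 highest and 8 lowest ratios among genes of at least 10 CPM in at least 1 library compared. It leaves out receptor and immunoglobulin segments, ribosomal, mitochondrial and unnamed genes. It adds up to 2 highest and 2 lowest members of each list described, and Sting1, Cgas, Ifnb1, Ifng, Gzmb, Pdcd1, Tcf7 and Mki67. Some genes of the fixed lists are not reported here. The procedure was tested on Poisson counts simulated from the mean profile of all libraries, with known folds put into the induced STING-expressing library. The STING-expressing libraries with and without induction were then compared. These draws hold no variation between libraries and no co-regulation of genes. They check the computation, and not how the intervals and percentiles behave on real libraries. For 50 genes each with true folds of 1.25, 1.5, 2 and 4 among 7816 genes, the median log2 ratios found were 0.318, 0.577, 0.985 and 1.967, and 88%, 96%, 96% and 98% of the intervals held the true value. In a step on 11032 genes, a list of 50 genes changed 1.25-fold lay at percentile 100, and 4 of 100 unchanged lists of 30 genes fell outside the central 95%.

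Alternatives changed 1 choice at a time, except for 2. The sum over all barcodes drops the cell filter and also takes in the left-out non-T cells. The stricter filter was followed by a new clustering and naming, which kept cells that the main run leaves out, among them 232, 137, 1 and 0 dendritic cell-like and 15, 121, 5 and 12 neutrophil-like cells in the order used in the report. They covered scaling by TMM factors (edgeR 4.0.16) or by median-of-ratios size factors (DESeq2 1.42.0, R 4.3.3), all barcodes, a stricter filter (1000 genes, 10% mitochondrial), no cells above 2.5 times the median UMI count, the mean of each cell's own CPM, and cells thinned to 3000 UMIs. They also covered pseudocounts of 0.1 and 5 CPM, other minimum levels for list members, cycling-like clusters alone or left out, and clustering at resolution 0.4 or 1.2, with the lists left in or on thinned cells. Added after seeing the data were leaving out the 6% of cells with the highest Scrublet scores, leaving out an unnamed cluster led by NK receptor genes, and list medians within clusters with the median of these over clusters, called the middle, list medians with the share of each cluster in the summed UMIs set to its mean over libraries, and the stricter filter with the cell names of the main run. Gene positions relative to each other were taken from GENCODE vM21 on GRCm38.p6, a different build from the one the counts were made with, so no coordinates are given. Figures were drawn with matplotlib 3.10.9.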

Results

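The data were single-cell RNA counts of CD8+ T cells re-isolated from tumours of mice. The tumours were grown from Lewis lung carcinoma cells, a mouse lung cancer line, in which the DNA sensor cGAS can be switched on through a Tet-On promoter. cGAS makes the cyclic dinucleotide cGAMP, the ligand of STING, and the series title concerns the effect of cGAMP from cancer cells on tumour CD8+ T cells. STING-expressing and STING-deficient OT-I cells, CD8+ T cells whose transgenic receptor recognises an ovalbumin peptide, were transferred together 3 days after tumour injection and sorted 6 days later as live CD8+ cells by their CD45 allele. The 4 libraries were STING-expressing or STING-deficient cells, each with cGAS induced or not, with 1 library per group. There are therefore no replicates, no difference below has a replicate check, and every interval is a 95% interval that covers counting error only.

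The libraries held 18822 barcodes and 214054710 unique molecules (UMIs) for STING-expressing cells with induction, and 14266 barcodes and 185393484 UMIs without it. For STING-deficient cells they held 16781 barcodes and 203303108 UMIs with induction, and 15566 barcodes and 189267181 UMIs without it. Levels are given in CPM, the UMIs of a gene per 1000000 UMIs summed over the kept cells, of which there were 17456, 12632, 16564 and 15345 in the same order. A sum of 0 UMIs allows a level of up to 0.0149 to 0.0185 CPM in these libraries. A gene list is described by the median log2 ratio of its members and by that median's percentile among 10000 random lists matched on mean expression.

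The first question was whether the targeted gene followed the labels. Sting1, which encodes STING, stood at 71.0 CPM (69.9 to 72.2) in STING-expressing and at 69.4 CPM (68.3 to 70.6) in STING-deficient cells with induction. Without induction it stood at 69.6 CPM (68.3 to 70.9) and 67.2 CPM (66.1 to 68.4), so its level did not separate the genotypes. The labels call the cells knockout without describing the allele, and a 3' tag outside an altered part of the gene checks nothing, so the genotype rests on the labels alone. Cgas, the T cells' own copy of the sensor gene, lay between 37.5 and 42.9 CPM in the 4 libraries. No UMI of Ifnb1, the gene of interferon beta, was counted in kept cells of any library.

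The comparison with and without induced cGAS in STING-expressing cells asks how the cells differ when cGAS of the tumours was induced. The level of cGAMP was not measured here. Genes of the type I interferon response were higher with induction: all 53 measured members, with a median log2 ratio of 0.45 (0.43 to 0.47) at percentile 100 of the random lists. Ifit3 and Ifit1, which encode antiviral RNA-binding proteins, were 2.04-fold (1.95 to 2.13) and 1.98-fold (1.92 to 2.05) higher, while Epsti1 was 1.03-fold (1.02 to 1.04) higher. Oasl2, of the oligoadenylate synthetase family, stood at 27.5 against 13.9 CPM, and outside the list Ifi204, a DNA-binding protein of the p200 family, at 25.2 against 12.7 CPM and Rnf213, a ubiquitin ligase of antimicrobial defence, at 171 against 91.9 CPM. Genes of glycolysis and the hypoxia response were lower with induction: all 26 members, with a median of -0.56 (-0.58 to -0.54) at percentile 0.

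Bnip3, a mitophagy receptor induced by hypoxia, stood at 24.0 against 73.4 CPM, which is 0.327-fold (0.317 to 0.339), and Ankrd37, another hypoxia-induced gene, at 0.372-fold (0.356 to 0.389). Aldoc, a glycolytic aldolase outside the list, stood at 3.99 against 16.4 CPM. Targets of p53 and apoptosis genes were lower in 19 of 23 members, with a median of -0.40 at percentile 0. Ccng1, the p53 target cyclin G1, stood at 108 against 211 CPM, while Bak1, a pore-forming protein of apoptosis, was 1.43-fold (1.40 to 1.46) higher. Ribosomal protein genes were lower in 40 of 43 members, with a median of -0.14 at percentile 0.1, led by Rps29 at 0.658-fold (0.654 to 0.661); under TMM scaling (trimmed mean of M values) the median was -0.06. T cell activation genes were lower in 18 of 30 members, with a median of -0.091 at percentile 0.64 that came to 0.0 under median-of-ratios scaling. In that list Tfrc, the transferrin receptor, stood at 0.634-fold (0.625 to 0.643) and Nr4a1, an early gene of receptor signalling, at 1.30-fold (1.29 to 1.31). Cell cycle genes had a median of -0.060 at percentile 1.95, which turned to 0.015 under TMM and 0.028 under median-of-ratios scaling. Under these scalings the median of all 11258 genes also moved, from -0.039 to 0.033 and 0.045, so the list stayed below it. Cenpf, a centromere protein, stood at 0.715-fold (0.691 to 0.740) and Mcm4, a subunit of the replicative helicase, at 1.32-fold (1.29 to 1.34).

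Mitochondrially encoded genes were higher in 10 of 13 members, with a median of 0.16 at percentile 99.5, and mt-Cytb stood at 7583 against 5425 CPM. The median share of mitochondrial UMIs per kept cell was 7.68% with and 6.99% without induction. Genes of the cGAS-STING pathway had a median of 0.067 at percentile 98.2, which was 0.134 under TMM scaling, and Samhd1, a nucleotide hydrolase, was 1.23-fold (1.22 to 1.24) higher. Interferon gamma response genes had a median of 0.075 at percentile 99.7, which was 0.152 under TMM scaling. Ifi47, an immunity-related GTPase, stood at 241 against 173 CPM, and Tgtp2, of the same family, at 34.0 against 39.8 CPM. Residency genes had a median of 0.081 at percentile 99.2 but a mean of -0.025, with Cxcr6, a chemokine receptor of resident T cells, at 0.685-fold (0.677 to 0.693). Genes of the integrated stress response had a median of 0.042 at percentile 97.9 but a mean of -0.19, with Asns, asparagine synthetase, at 24.1 against 48.3 CPM.

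The medians of the other lists lay within the central 95% of the random lists. They were 0.006 for the NF-kB response and 0.029 for stem-like and memory genes, and -0.058 for cytotoxic, -0.081 for inhibitory receptor, -0.016 for oxidative phosphorylation and -0.041 for dissociation genes, of which the last 4 turned positive under median-of-ratios scaling and the dissociation list had a mean of 0.019. Single members of these lists stood further apart. Nfkbie, an inhibitor of NF-kB, was 1.53-fold (1.48 to 1.57) higher. Gzmf, a granzyme, stood at 0.680-fold (0.646 to 0.716), Entpd1, the ectonucleotidase CD39, at 0.730-fold (0.694 to 0.768), and the heat shock gene Hspa1a at 0.507-fold (0.493 to 0.521). Gzmb, granzyme B, stood at 7521 against 6363 CPM, Pdcd1, the inhibitory receptor PD-1, at 305 against 238 CPM, and Ifng, interferon gamma, at 1977 against 1822 CPM. Tcf7, a transcription factor of stem-like T cells, stood at 81.8 against 75.6 CPM and Mki67, a proliferation marker, at 331 against 392 CPM. By the ranking of all genes, Tppp3 and Nccrp1 were 2.46-fold (2.27 to 2.66) and 2.08-fold (1.98 to 2.18) higher. Serpine2, a protease inhibitor, and Tnfsf4, the OX40 ligand, stood at 0.350-fold (0.337 to 0.364) and 0.357-fold (0.336 to 0.380). Cxcl2, a chemokine that also led the neutrophil-like cluster, stood at 5.28 against 18.2 CPM where neutrophil-like cells were 0.40% against 4.50% of clustered cells. Heph stood at 65.1 against 199 CPM, a count that is uncertain because a processed pseudogene of Rpl17 lies inside the gene on the same strand (GRCm38.p6, GENCODE vM21). Cadps2 stood at 1.17 against 34.1 CPM, and the ratio of its UMIs to those of Fnbp1l ran from 3.84 to 5.85 across clusters without induction.

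Within the 9 kept clusters of at least 100 cells per library, a comparison chosen after seeing the data, the interferon median ran from 0.249 to 0.671 with a middle of 0.296. The glycolysis median ran from -0.592 to -0.023 with a middle of -0.234 and the p53 median from -0.594 to 0.076 with a middle of -0.066, so each of these lists differed less in the middle cluster than in the summed cells. Unlike members of both interferon lists, genes of the glycolysis, p53 and cell cycle lists were open to the clustering, and Bnip3, Phlda3 and Mcm2 are among those leading clusters. Within-cluster and equal-mix medians of those lists can be smaller for that reason alone. They do not decide whether the mix lies behind the summed values. Interferon genes outside the lists were not left out of the clustering. A cluster led by Tcf7 also had Ifit1bl1, Ifit3 and Ifi213 among its leading genes. Within-cluster and equal-mix medians of the interferon list may therefore be smaller for such a reason too. The libraries differed in the mix of clusters. A cluster led by Il17a, Serpine2 and Bnip3 held 4.67% of clustered STING-expressing cells with and 14.6% without induction. Serpine2 and Bnip3 are themselves among the genes lower with induction, so this share is not separate evidence. With the mix of clusters set equal in all libraries, also chosen after seeing the data, the interferon, glycolysis and p53 medians were 0.321, -0.278 and -0.156, the activation median 0.02 and the residency median -0.009. Within clusters the activation median lay above 0 in 7 of 9, with a middle of 0.026. In 8 of the 17 lists the middle had the opposite sign to the summed median, namely in this list, in the cell cycle (0.027) and residency (-0.004) lists and in 5 whose summed medians lay within the central 95%. These were the inhibitory receptor (0.053), cytotoxic (0.009), oxidative phosphorylation (0.015), dissociation (0.103) and stem-like (-0.110) lists. The same held for 5 lists in STING-deficient cells, for 5 and 2 between genotypes with and without induction and for 4 in the difference of the inductions. Summed over all barcodes, which includes the left-out non-T cells, Oasl2 and Ifi204 turned to log2 ratios of -0.06 and -0.10 and the interferon gamma list to -0.006, and in cycling-like clusters alone the p53 median was -0.032, the residency median -0.014, and Asns, Gzmf, Hspa1a and Tcf7 turned to 0.084, 0.53, 0.24 and -0.24.

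**Figure D1:**
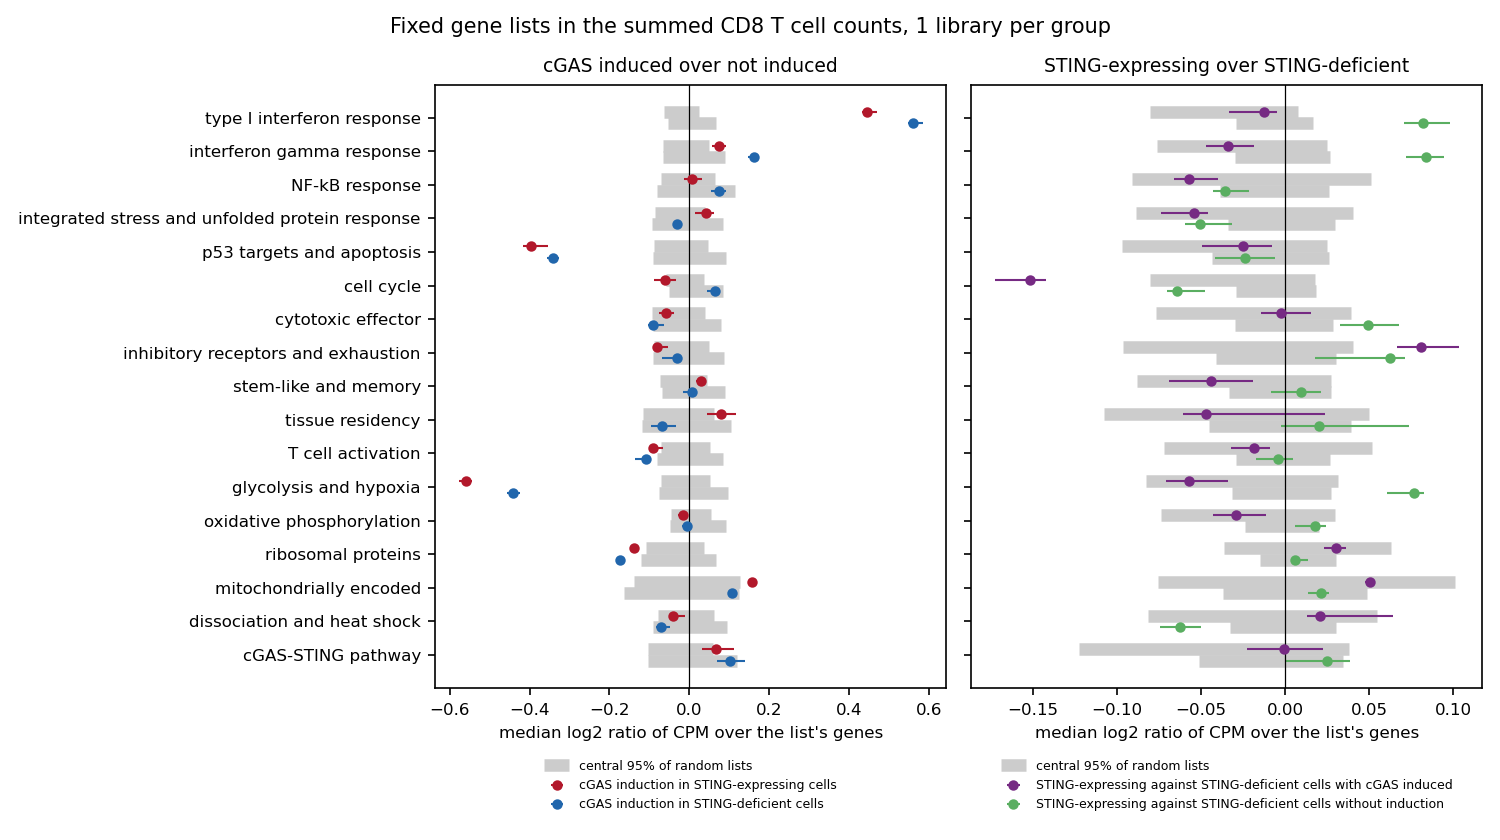
Median log2 ratio of each fixed gene list (x axis, log2 of the CPM ratio) in the comparisons between libraries, with bars for the 95% interval from counting error alone and grey bands for the central 95% of random lists. The type I interferon median was 0.45 and 0.56 with induction in STING-expressing and STING-deficient cells, and the glycolysis and hypoxia median -0.56 and -0.44; the cell cycle median in STING-expressing cells, -0.060, turned positive under other scalings.

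The same comparison in STING-deficient cells shows the response where the T cells are described as lacking STING. All 53 members of the type I interferon list were higher with induction here too, with a median of 0.56 (0.55 to 0.59) at percentile 100. Ifit3 was 2.29-fold (2.19 to 2.39), Oasl2 2.27-fold (2.16 to 2.38), Ifi204 2.23-fold (2.12 to 2.35) and Rnf213 2.49-fold (2.45 to 2.54) higher, and Epsti1 1.05-fold (1.04 to 1.07). Interferon gamma response genes were higher in 24 of 32 members, with a median of 0.16 at percentile 100 and Ifi47 at 280 against 173 CPM. Glycolysis and hypoxia genes were lower in 25 of 26 members, with a median of -0.44 (-0.46 to -0.43) at percentile 0, Bnip3 at 0.358-fold (0.347 to 0.371) and Ankrd37 at 0.386-fold (0.370 to 0.404).

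The p53 and apoptosis list was lower in 19 of 23 members, with a median of -0.34 at percentile 0, Ccng1 at 0.524-fold (0.515 to 0.533) and Bak1 at 1.41-fold (1.38 to 1.44). Ribosomal protein genes were lower in 35 of 43 members, with a median of -0.17 at percentile 0.06. T cell activation genes were lower in 19 of 30 members, with a median of -0.11 at percentile 0.6. Il2, interleukin 2, stood at 53.5 against 95.5 CPM and Nr4a1 at 793 against 540 CPM. The other medians lay within the central 95% of the random lists, from -0.090 for cytotoxic genes to 0.108 for mitochondrially encoded genes. Among them, integrated stress response, inhibitory receptor and oxidative phosphorylation genes had medians of -0.031, -0.031 and -0.006 that turned positive under TMM scaling, and residency genes a median of -0.069 with a mean of 0.002. Members of these lists included Mcm2, of the replicative helicase, at 1.45-fold (1.41 to 1.48), Hmgb2, a chromatin protein of dividing cells, at 0.729-fold (0.725 to 0.733) and Tigit, an inhibitory receptor, at 0.672-fold (0.653 to 0.692). Ccr7, a lymph node homing receptor, stood at 0.592-fold (0.574 to 0.611), Asns at 0.478-fold (0.461 to 0.496), Socs3, a feedback inhibitor of cytokine signalling, at 2.18-fold (2.10 to 2.27) and Hspa1a at 0.543-fold (0.529 to 0.557).

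Gzmb stood at 7700 against 6359 CPM, Pdcd1 at 323 against 237 CPM, Ifng at 2435 against 2215 CPM, Tcf7 at 94.1 against 75.1 CPM and Mki67 at 400 against 380 CPM. Tppp3 was 2.68-fold (2.48 to 2.89) higher, and Serpine2, Tnfsf4 and Aldoc stood at 0.267-fold (0.257 to 0.277), 0.283-fold (0.265 to 0.302) and 0.290-fold (0.267 to 0.315). Heph, whose count is uncertain as above, stood at 43.9 against 123 CPM. Cadps2, Fnbp1l and Ppp2r3a stood at 1.24, 0.427 and 5.44 CPM with induction and at 77.3, 15.8 and 24.97 CPM without it, and across clusters without induction the ratio of Cadps2 UMIs ran from 4.35 to 5.48 to those of Fnbp1l and from 2.65 to 4.18 to those of Ppp2r3a.

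The induced STING-deficient library also stood apart from the other 3. Cmss1 was at 260 CPM there and at 43.9 to 64.3 CPM elsewhere, mt-Nd6 at 77.5 CPM against 28.7 to 37.7 CPM, and the histone genes H4c4 and H1f5 at 25.4 and 34.6 CPM against 9.78 and 15.4 CPM in its uninduced counterpart. Ccl5, a chemokine of effector T cells, was at 828 CPM there and at 1269 to 1456 CPM elsewhere. In cycling-like clusters alone the interferon median was 0.331 and the glycolysis, p53 and ribosomal protein medians were -0.018, -0.094 and -0.024, while Ccr7, Hspa1a, Ifng and Tcf7 turned to log2 ratios of 0.073, 0.37, -0.054 and -0.071. Within the 9 clusters the interferon median ran from 0.297 to 0.819 with a middle of 0.429, the glycolysis median from -0.366 to 0.129 with a middle of -0.169 and the p53 median from -0.530 to 0.041 with a middle of -0.103, each nearer 0 than the summed value. The limits on within-cluster and equal-mix values of these lists given above hold here too. The cluster led by Il17a, Serpine2 and Bnip3 held 4.54% of clustered STING-deficient cells with and 16.5% without induction. With the mix of clusters set equal the interferon, glycolysis and p53 medians were 0.384, -0.185 and -0.216, and the activation median was 0.021.

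**Figure D2:**
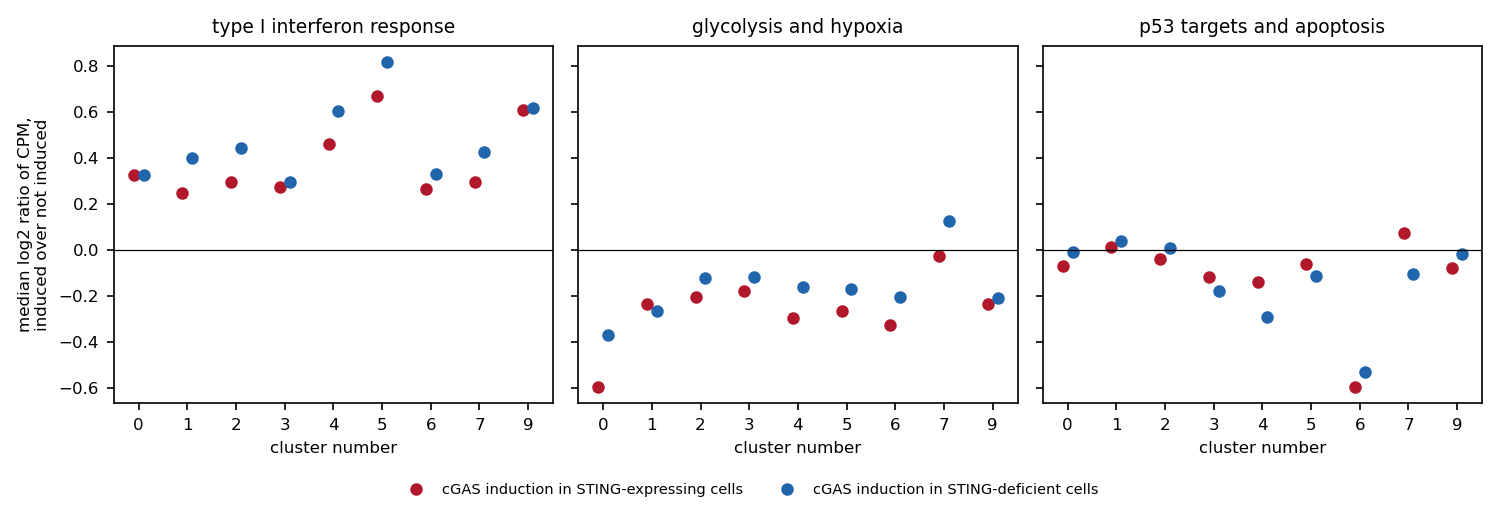
Median log2 ratio of CPM with over without induction (y axis) of the type I interferon, glycolysis and p53 lists within each kept cluster of at least 100 cells per library (x axis, cluster number), 1 point per genotype and no error drawn. All interferon medians lay above 0, between 0.249 and 0.819, and the p53 medians of cluster 6 were the lowest of that list, with -0.594 in STING-expressing cells.

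**Figure D3:**
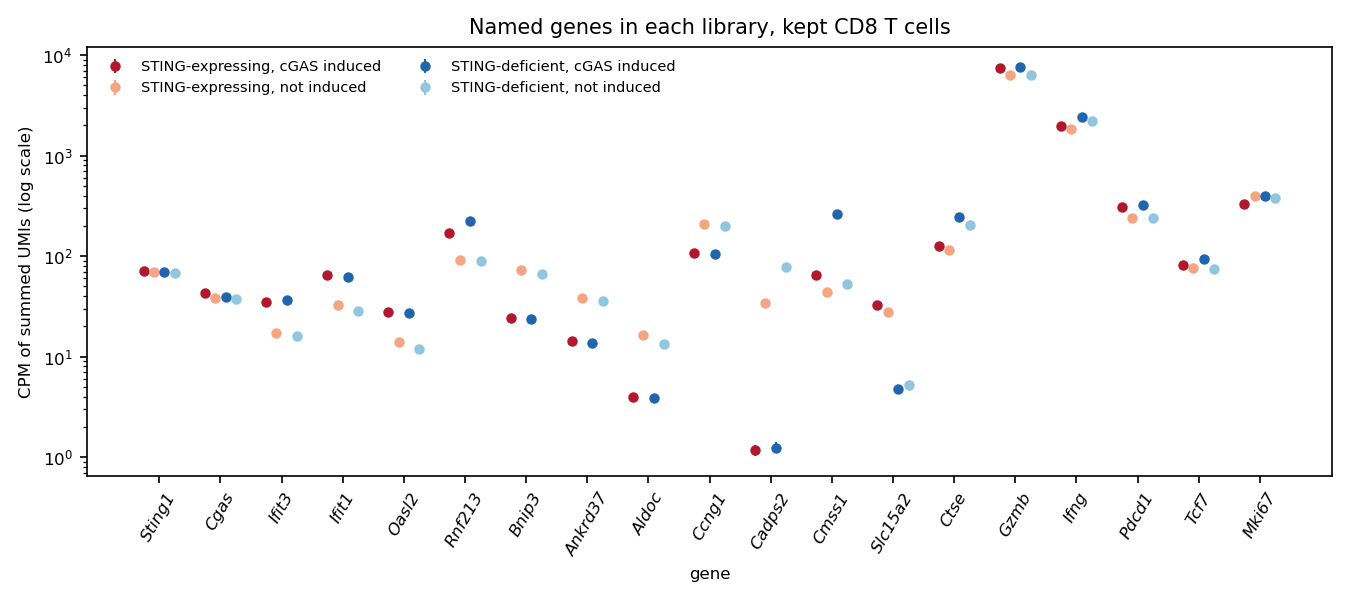
CPM (y axis, log scale) of named genes in each of the 4 libraries, with bars for exact Poisson 95% intervals of the summed UMIs. Sting1 lay between 67.2 and 71.0 CPM in all 4 libraries, Ifit3 was at 34.7 and 36.8 CPM with induction against 17.0 and 16.1 CPM without it, and Bnip3 at 24.0 and 23.8 CPM against 73.4 and 66.5 CPM.

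With cGAS induced, the comparison of STING-expressing with STING-deficient cells, described as transferred together, asks which genes differ with the genotype of the sorted cells. Too few members of the OT-I receptor marker set were counted to check that every kept cell was a transferred cell. The STING-expressing sorts held more non-T cells, as given below. Other CD8 T cells among their kept cells could therefore add to any difference between genotypes, which was not tested. Whether both libraries of a condition came from the same mice is not given in the sources used here. Cell cycle genes were lower in STING-expressing cells in 36 of 40 members, with a median of -0.15 at percentile 0 over the summed cells, whereas within the 9 clusters the median lay above 0 in 6, with a middle of 0.022, and with the mix of clusters set equal it was -0.081. Bub1b, a spindle checkpoint kinase, and Tk1, thymidine kinase, stood at 0.636-fold (0.601 to 0.672) and 0.692-fold (0.668 to 0.717), Mki67 at 0.827-fold (0.818 to 0.835), and Hmgb2 at 1.24-fold (1.23 to 1.24). Genes of inhibitory receptors and exhaustion were higher in 17 of 25 members, with a median of 0.081 at percentile 99.9, including Rgs16, a regulator of G protein signalling, at 1.41-fold (1.39 to 1.43) and Eomes, a T-box transcription factor, at 1.36-fold (1.30 to 1.42). The type I interferon median was -0.013 at percentile 87.6, with 21 members higher and 32 lower, and it turned to 0.026 under TMM and 0.045 under median-of-ratios scaling. Trim30d stood at 1.41-fold (1.36 to 1.47), Ifi208 at 0.522-fold (0.509 to 0.535), and Bst2, the virion-retaining protein tetherin, at 0.749-fold (0.734 to 0.764).

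The other 14 lists had medians from -0.057 for the NF-kB response and for glycolysis and hypoxia to 0.050 for mitochondrially encoded genes, within the central 95% of the random lists. The interferon gamma, p53, cytotoxic, activation, oxidative phosphorylation and cGAS-STING medians, from -0.034 to -0.001, turned positive under both other scalings, and the NF-kB, integrated stress, stem-like and residency medians, from -0.057 to -0.044, came to 0.0 or above under median-of-ratios scaling. The cytotoxic, stem-like, residency and activation lists had means above 0, of 0.052, 0.008, 0.027 and 0.008. Slc15a2, a peptide transporter, stood at 32.7 against 4.78 CPM, Mid1, a ubiquitin ligase, at 13.0 against 3.89 CPM, Rab4a, a GTPase of endosome recycling, at 11.5 against 3.77 CPM and Marveld2, a tight junction protein, at 13.0 against 7.12 CPM. Fcer1g, a gene of myeloid cells that is also in the NK marker set, stood at 12.2 against 2.36 CPM. Cd74, a gene of antigen-presenting cells, stood at 23.6 against 7.10 CPM. In these libraries 6.79% of clustered STING-expressing and 0.684% of STING-deficient cells fell in left-out non-T clusters, and RNA from such cells at its estimated level matched 76.0% of the Cd74 difference and 44.8% of that of Fcer1g. Ctse, cathepsin E, stood at 0.514-fold (0.506 to 0.522). Ctse, Rgs16 and Fcer1g lie on chromosome 1 within 100 expressed genes of Ptprc, the gene of CD45, by whose allele the genotypes were sorted (GRCm38.p6, GENCODE vM21). Ifi208 lies on the same chromosome, 107 expressed genes from Ptprc. Its difference therefore cannot be told apart from a difference linked to Ptprc.

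Ifng was lower in STING-expressing cells, at 0.812-fold (0.808 to 0.815), and Tcf7 stood at 0.869-fold (0.851 to 0.887), whereas Gzmb, at 7521 against 7700 CPM, turned higher under the other scalings, and Pdcd1 stood at 0.945-fold (0.935 to 0.956). For several genes the induced STING-deficient library stood apart from the other 3. Pfdn1, a chaperone subunit, and Cd40lg, the CD40 ligand, were lowest there, at 54.2 and 40.6 CPM against 88.2 and 64.0 CPM, as was Ccl5. Cmss1, H4c4, H3c3, Patl2, Map3k12 and Otud7a were highest there, with Cmss1 at 0.247-fold (0.242 to 0.252) and Patl2 at 0.455-fold (0.436 to 0.475) in STING-expressing cells. Klrg1, a receptor of effector cells, stood at 1.39-fold (1.30 to 1.49), and Rgs2 and Rgs1 at 405 against 270 CPM and 537 against 409 CPM. Without the cycling-like clusters the cell cycle median was -0.024, and in cycling-like clusters alone Ifng turned to a log2 ratio of 0.047.

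Without induction, the same comparison gives the background to the one above. In STING-expressing cells, type I interferon genes were higher in 43 of 53 members, with a median of 0.082 (0.071 to 0.098) at percentile 100, which was 0.067 after RNA of left-out cells at its estimated level was taken off, and interferon gamma response genes in 24 of 32, with a median of 0.084 at percentile 100 that was 0.078 after the same step. Trim30d stood at 1.41-fold (1.34 to 1.49), Gbp2, a guanylate-binding protein, at 159 against 133 CPM and Tgtp2 at 39.8 against 31.9 CPM, while Ifi208 stood at 0.640-fold (0.618 to 0.663). The limit given above for Ifi208 holds here too. Glycolysis and hypoxia genes were higher in 20 of 26 members, with a median of 0.077 at percentile 100, including Egln3, an oxygen-sensing hydroxylase, at 26.5 against 21.2 CPM and Bnip3 at 1.10-fold (1.08 to 1.13). Inhibitory receptor genes had a median of 0.062 at percentile 99.97, with Rgs16 at 1.32-fold (1.31 to 1.34) and Tnfrsf9, the costimulatory receptor 4-1BB, at 0.880-fold (0.873 to 0.886).

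Cytotoxic genes had a median of 0.049 at percentile 99.9, with Klrk1, the activating receptor NKG2D, at 1.17-fold (1.15 to 1.18), and with Ifng and Ccl3, a chemokine, at 0.822-fold (0.818 to 0.826) and 0.828-fold (0.824 to 0.832). Cell cycle genes were lower in 32 of 40 members, with a median of -0.064 at percentile 0 and Mcm2 at 0.878-fold (0.854 to 0.902). Integrated stress response genes had a median of -0.051 at percentile 0.16 but a mean of 0.036. Dissociation genes, immediate early and heat shock genes that respond to tissue digestion, had a median of -0.063 at percentile 0.03, with Junb and Jund, subunits of AP-1, at 0.806-fold (0.798 to 0.815) and 0.827-fold (0.823 to 0.832). The other 9 medians lay from -0.036 for the NF-kB response to 0.025 for the cGAS-STING pathway, and those of stem-like and ribosomal protein genes, 0.0095 and 0.0055, turned negative under median-of-ratios scaling. The means of the stem-like and cGAS-STING lists were -0.005 and -0.007. Gzmb, Pdcd1 and Tcf7 stood at 1.00-fold (0.998 to 1.00), 1.01-fold (0.991 to 1.02) and 1.01-fold (0.982 to 1.03), ratios whose sign turned under the other scalings, and Mki67 at 1.03-fold (1.02 to 1.04).

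Slc15a2 stood at 27.9 against 5.22 CPM, Mid1 at 12.8 against 3.38 CPM, Rab4a at 10.7 against 5.53 CPM, Marveld2 at 11.1 against 7.32 CPM and Ctnna1, alpha-catenin, at 41.9 against 28.1 CPM. Ctse and Lrmp stood at 0.560-fold (0.550 to 0.570) and 0.556-fold (0.542 to 0.569), and Il17a, interleukin 17A, at 13.8 against 29.8 CPM. Pold4, a DNA polymerase subunit, and Igfbp7, a secreted binding protein, stood at 0.550-fold (0.518 to 0.584) and 0.615-fold (0.587 to 0.645). Cxcl2 and Cd74 stood at 18.2 against 1.34 CPM and at 15.7 against 10.2 CPM, where 11.1% and 0.968% of clustered cells were in left-out non-T clusters and their RNA at its estimated level matched 80.2% and 181% of these differences. Heph, uncertain as above, stood at 1.62-fold (1.59 to 1.64), and Cadps2, Fnbp1l and Ppp2r3a at 0.442-fold (0.428 to 0.456), 0.470-fold (0.439 to 0.502) and 0.557-fold (0.529 to 0.585). Summed over all barcodes, left-out cells included, the interferon median was 0.347, and the integrated stress response, cytotoxic and dissociation medians turned to 0.043, -0.025 and 0.016. In cycling-like clusters alone the interferon and cell cycle medians were 0.026 and -0.025, and the inhibitory receptor median was 0.005 over members of at least 10 CPM.

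The difference of the inductions, the log2 ratio in STING-expressing minus that in STING-deficient cells, asks whether the response goes with STING in the T cell; it was not tested. The type I interferon difference had a median of -0.11 (-0.13 to -0.09) at percentile 0.01, with 40 of 53 members below 0, and it was -0.068 under TMM and -0.041 under median-of-ratios scaling. Bst2 and Samd9l, an antiviral translation regulator, had differences of -0.37 and -0.31, and Xaf1, an apoptosis regulator, of 0.30. The interferon gamma difference had a median of -0.15 at percentile 0, with 23 of 32 members below 0, and it was -0.081 under median-of-ratios scaling; Gbp10 and Tgtp2 had differences of -0.43 and -0.40. Glycolysis and hypoxia genes had a median difference of -0.098 at percentile 0.65, which was -0.032 under median-of-ratios scaling, with Pkm and Pfkl, glycolytic enzymes, at -0.38 and 0.50.

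Cell cycle genes had a median difference of -0.099 at percentile 0.2, with Bub1b at -0.50, Hmgb2 at 0.29 and Mki67 at -0.32, and the median was -0.027 under median-of-ratios scaling, 0.032 without the cycling-like clusters and 0.022 as the middle within clusters. The limit on within-cluster values of this list given above holds here too. Dissociation genes had a median difference of 0.11 at percentile 99.97, with Junb at 0.50 and the heat shock gene Hsph1 at 0.33, and the median was 0.011 over all barcodes. The other 12 medians lay from -0.055 for residency genes to 0.049 for mitochondrially encoded genes, whose mean was -0.011, and those of the NF-kB, integrated stress, activation, oxidative phosphorylation and cGAS-STING lists turned from negative to positive under both other scalings, the activation list with a mean of 0.017. Gzmb, Ifng and Sting1 had differences of -0.035, -0.019 and -0.017, each turning positive under median-of-ratios scaling, Pdcd1 of -0.088 and Tcf7 of -0.21.

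Among single genes, Fnbp1l, Cadps2 and Ppp2r3a had differences of 1.18, 1.11 and 0.82, Cd74 of 1.03 and Cxcl2 of -1.43, with the limits given for them above. Pold4 had a difference of 0.94, and Pfdn1, Cox16, an assembly factor of cytochrome oxidase, and Nrgn, a calmodulin-binding protein, of 0.75, 0.65 and 0.65. Cmss1, Patl2, H4c4, Pde6h, H3c3, Map3k12, Plcxd3 and mt-Nd6 had differences of -1.74, -1.34, -1.26, -1.16, -1.10, -0.99, -0.96 and -1.10, each with its highest level in the induced STING-deficient library. Rgs1 and Rgs2 had differences of 0.39 and 0.40. In cycling-like clusters alone the type I interferon median difference was -0.02.

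Clustering of 65103 cells gave 14 clusters, of which 2 were named cycling CD8 T-like and 4 were left out as non-T cells. Cycling-like cells made up 16.8% (16.2 to 17.3) and 16.6% (16.0 to 17.3) of kept STING-expressing cells with and without induction, and 17.9% (17.4 to 18.5) and 17.0% (16.4 to 17.6) of kept STING-deficient cells. A cluster led by Ung and Mcm genes of DNA replication, kept out of this class by naming thresholds set after seeing the data, held 14.9%, 8.45%, 15.4% and 9.67% of clustered cells in the same order. Macrophage or monocyte-like cells were 5.07% and 5.20% of clustered cells in the sorts of STING-expressing cells and 0.264% and 0.290% in those of STING-deficient cells. Neutrophil-like cells were 0.40%, 4.50%, 0.342% and 0.587%, dendritic cell-like cells 234, 140, 1 and 0 in number, and fibroblast or endothelial-like cells 0.069%, 0.373%, 0.072% and 0.090%. The sort by CD8 and CD45 allele can set these shares, and at resolution 0.4 no macrophage cluster met the naming rule.

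Markers of other cell types were also counted in kept cells. In STING-expressing against STING-deficient cells with and without induction, the median log2 ratio was 0.33 and 0.81 for macrophage or monocyte markers, 0.83 and 0.31 for dendritic cell markers and 0.62 and 0.40 for NK markers. An unnamed kept cluster led by gamma delta constant and NK receptor genes held 142 and 83 STING-expressing but 14 and 10 STING-deficient cells, and without it the NK medians were 0.46 and 0.020. Over all kept cells the median was 0.044 and -0.068 for CD4 T cell, 0.152 and -0.109 for gamma delta T cell, the former with a mean just below 0, and 0.164 and -0.028 for tumour or epithelial markers. The gamma delta set was described over 3 of its 7 genes. It names the constant genes Tcrg-C, whereas those leading the unnamed cluster are named Trgc, so its median is a poor measure of such cells. For induction in STING-expressing and STING-deficient cells the median was 0.031 and -0.001 for CD8 T cell, -0.143 and -0.015 for cycling, -0.026 and -0.068 for stem-memory, -0.22 and -0.30 for terminally exhausted and 0.042 and -0.007 for circulating effector markers. For other cell types it was -0.136 and -0.363 for CD4 T cell, 0.240 and -0.261 for NK and -0.078 and -0.295 for dendritic cell markers. Macrophage or monocyte markers had -0.215 and -0.068, gamma delta T cell markers -0.097 and -0.357, and tumour or epithelial markers 0.203 and 0.125. In STING-expressing cells the means of the stem-memory and circulating effector markers, 0.013 and -0.004, had the opposite sign. B cell, neutrophil, fibroblast, erythroid and OT-I receptor marker sets had fewer than 3 members of at least 1 CPM. Among the last, Trbv12-1, a beta-chain segment on the OT-I receptor list, lay between 21.7 and 29.6 CPM.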

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

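The tests of what could lie behind the interferon pattern were chosen after its values had been seen. In 3 lists the induction median lay on opposite sides of 0 in the genotypes. The cell cycle list had medians of -0.060 and 0.063 in STING-expressing and STING-deficient cells and a median difference of -0.099. The integrated stress response list had 0.042 and -0.031 with a difference of -0.007, and the residency list 0.081 and -0.069 with a difference of -0.055. These differences, and those of the genes that follow, were not tested, since each group is 1 library, and the first list turned positive in STING-expressing cells under both other scalings. In all 3 lists the middle of the medians within clusters lay on the same side of 0 in both genotypes, though cell cycle genes could themselves shape these clusters.

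Among the named genes, 12 had induction ratios in opposite directions in the genotypes, each of at least 0.1 with counting intervals that exclude 0. The difference was positive for Cd74 (1.033), Pold4 (0.938), Nrgn (0.645), Rgs2 (0.401) and Rgs1 (0.392). It was negative for Patl2 (-1.344), Pde6h (-1.161), H3c3 (-1.097), Map3k12 (-0.994), Plcxd3 (-0.957), Bub1b (-0.504) and Tgtp2 (-0.404). Patl2, Pde6h, H3c3, Map3k12, Plcxd3 and Bub1b had their highest level in the induced STING-deficient library.

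The type I interferon list was also higher with induction in cells that the comparisons leave out. In macrophage or monocyte-like cells of the STING-expressing sorts (949 and 739 cells) all 53 members were higher, with a median log2 ratio of 0.561 (0.518 to 0.60, counting error only). In neutrophil-like cells of the same sorts (75 and 639 cells) 50 of 53 members were higher, with a median of 0.290 (0.261 to 0.401). T cell RNA was present in both, since CD8 T cell markers stood at 33.8% to 39.2% of their level in kept cells. With it taken off, all 53 members were higher in the first, with a median of 0.63, and 44 of 53 in the second, with a median of 0.23.

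The interferon list was thus higher with induction in T cells of both genotypes and in myeloid-like cells. A shift in the mix of T cell clusters is argued against as the whole cause, since the lowest median within any cluster of at least 100 cells per library was 0.249 over both genotypes. RNA from left-out cells is argued against as well, since at its estimated level it gave 0.375% of the difference of the median list member. For the myeloid-like cells, T cell RNA as the main source is argued against, since it gave at most 15.94% of that member's difference. The 2 induced libraries cannot be told apart from the mice, the inducing treatment and the library handling that go with them, because no uninduced cell shares these. As a hypothesis, interferon or other signals made by other cells of the tumour after cGAS induction may reach T cells whether or not they carry STING; no measurement here separates this from those other causes. Several induced libraries per genotype, with mice given the inducing treatment but no inducible cGAS, would separate those causes, and blocking the interferon receptor on the T cells would test the hypothesis.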

How the results depend on the processing

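Under the alternatives fixed beforehand, 46 values of the main results moved beyond their counting interval and 47 did not. Of other lists and named genes, 1309 values moved without turning a called direction, 1862 did not move and 23 reversed. Under those chosen after seeing the data, 13 values of the main results and 201 others moved and 8 reversed. With induction, the type I interferon median stayed above 0 in both genotypes under every alternative summed over clusters, from 0.261 to 0.534 in STING-expressing and from 0.331 to 0.641 in STING-deficient cells. The values that follow are median log2 ratios unless another unit is named, and the cause was not tested except that summing all barcodes, and the new clustering after the stricter filter, add left-out non-T cells. With the cell names of the main run the stricter filter gave 0.444 and 0.558 for the interferon list with induction in STING-expressing and STING-deficient cells, -0.016 and 0.081 between genotypes with and without induction and -0.107 for the difference. Within a comparison no paired analysis was possible, because each group has only 1 library. Pairing over both genotypes or both conditions, as in an additive fit of genotype and induction over the 4 libraries, was not run. The planned removal of Scrublet calls was not run, because the caller marked at most 4 cells of a library. Depth enters through the counting intervals, and the choice of scaling and the missing replicates add uncertainty that these do not hold. Scaling moves all genes of a comparison nearly alike. Between genotypes with induction the median of 11258 genes went from -0.043 to -0.008 with TMM and 0.008 with median-of-ratios. For the difference of the inductions it went from -0.036 to 0.006 and 0.030. A change of sign under scaling therefore does not by itself change a list's place among other genes.

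For the interferon list in STING-expressing cells, induction gave 0.521 with TMM and 0.534 with median-of-ratios factors, 0.306 over all barcodes, 0.429 with the stricter filter, 0.404 without cells of high UMI count, 0.416 as the mean of cells, 0.422 on thinned cells, 0.407 with a pseudocount of 5 CPM, 0.261 in cycling-like clusters and 0.508 without them. In STING-deficient cells it gave 0.592 with TMM, 0.517 with a pseudocount of 5 CPM, 0.331 in cycling-like clusters, 0.641 without them and 0.547 without the 6% highest Scrublet scores. Between genotypes with induction it was 0.026 with TMM, 0.045 with median-of-ratios, 0.124 over all barcodes, 0.025 with the stricter filter and -0.038 without cycling-like clusters. Without induction it was 0.066 with median-of-ratios, 0.347 over all barcodes, 0.144 with the stricter filter, 0.069 with a pseudocount of 5 CPM and 0.026 in cycling-like clusters. The difference of the inductions was -0.068 with TMM, -0.041 with median-of-ratios, -0.230 over all barcodes, -0.151 with the stricter filter and -0.020 in cycling-like clusters. As the middle of the medians within clusters, induction gave 0.296 and 0.429 in STING-expressing and STING-deficient cells, the genotypes differed by 0.001 with and 0.062 without induction, and the difference of the inductions was -0.069. With the mix of clusters set equal, induction gave 0.321 and 0.384, and the genotypes differed by 0.066 without induction.

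Reversed lists for induction in STING-expressing cells were the cell cycle list at 0.015 with TMM and 0.028 with median-of-ratios, the activation list at 0.0 with median-of-ratios and 0.037 in cycling-like clusters, the interferon gamma list at -0.006 over all barcodes and -0.022 in cycling-like clusters, and the residency list at -0.014 in cycling-like clusters. Between genotypes without induction, all barcodes gave 0.043 for the integrated stress, -0.025 for the cytotoxic and 0.016 for the dissociation list. The cell cycle difference of the inductions was 0.032 without cycling-like clusters. Reversed as the middle within clusters were, for induction in STING-expressing cells, the cell cycle list at 0.027, the residency list at -0.004 and the activation list at 0.026, and the cell cycle list at 0.022 both between genotypes with induction and for the difference of the inductions. With the mix of clusters set equal, induction gave -0.009 for the residency and 0.02 for the activation list in STING-expressing cells and 0.021 for the activation list in STING-deficient cells.

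Reversed log2 ratios of genes for induction in STING-expressing cells were -0.10 for Ifi204 and -0.060 for Oasl2 over all barcodes, and in cycling-like clusters 0.084 for Asns, 0.532 for Gzmf, 0.242 for Hspa1a and -0.236 for Tcf7. In STING-deficient cells they were, in cycling-like clusters, 0.073 for Ccr7, 0.366 for Hspa1a, -0.054 for Ifng and -0.071 for Tcf7, and -0.0 for Ifng as the mean of cells. Between genotypes with induction, Ifng was at 0.047 in cycling-like clusters.

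Sting1 stood at 72.46 CPM over all barcodes and 73.38 CPM with TMM in induced and at 68.06 CPM with TMM in uninduced STING-expressing cells. The share of cycling-like cells in induced and uninduced STING-expressing cells was 15.61% and 15.62% at resolution 0.4, 18.16% and 17.39% at resolution 1.2, 14.04% and 14.43% with the lists used to cluster, 18.58% and 17.45% with the stricter filter, and 14.24% and 14.65% without the highest Scrublet scores. In induced and uninduced STING-deficient cells it was 19.32% and 17.99% at resolution 1.2, 15.38% and 14.58% with the lists used, 20.07% and 18.04% with the stricter filter, and 15.67% and 14.86% without the highest Scrublet scores.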

Other observations

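The tests of the genotype pattern and of the Cadps2 pattern, and the genes named for the myeloid cells, were chosen after the results were seen. Macrophage or monocyte-like cells, left out of the T cell comparisons, differed with induction in more than interferon genes. These cells also held T cell RNA: CD8 T cell markers stood at 39.2%, 34.9%, 6.39% and 17.8% of their level in kept cells, in the order used in the report, and the values that follow include it. In the STING-expressing sorts Arg1, arginase of immunosuppressive macrophages, stood at 314 CPM with and 1242 CPM without induction, which is 0.253-fold (0.244 to 0.261, counting error only). Nos2, inducible nitric oxide synthase, stood at 750 against 1070 CPM and Lyz2, lysozyme, at 1631 against 3303 CPM, whereas Ifit3 was 3.71-fold (3.41 to 4.22) and Isg15 1.67-fold (1.61 to 1.73) higher. Folds given for left-out cells include the pseudocount of 1 CPM, which their intervals do not. In the STING-deficient sorts, with 44 and 45 such cells, Arg1 stood at 411 against 2538 CPM, Nos2 at 723 against 2083 CPM and Ifit3 at 233 against 34.1 CPM. The chemokine gene Cxcl10 stood at 898 against 790 CPM in the former and at 1397 against 674 CPM in the latter.

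In neutrophil-like cells Rsad2, the antiviral enzyme viperin, stood at 3360 CPM with and 1750 CPM without induction in the STING-expressing sorts and at 4918 against 1595 CPM in the STING-deficient sorts. Ifit3 was 2.55-fold (2.30 to 2.83) and 3.66-fold (3.12 to 4.32) higher with induction. These values rest on 75, 639, 57 and 91 cells in the order used in the report, in which CD8 T cell markers stood at 33.8%, 38.15%, 26.3% and 29.2% of their level in kept cells.

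Of the genes of at least 10 CPM, 30 differed between genotypes by at least 0.3 on the log2 scale in the same direction with and without induction, 19 of them higher in STING-expressing cells. A strain segment carried around Ptprc is a candidate explanation for part of them, since 7, with Dbi, Ctse, Ube2t, Rgs16 and Fcer1g among them, lie within 100 expressed genes of Ptprc, against a mean of 0.897 and a highest count of 5 in 10000 random sets; at a least difference of 0.5, 3 of 12 did (7575 of 7585 genes were placed on GRCm38.p6). RNA of left-out cells, estimated from their profiles, gave 93.9% and 80.2% of the difference of Cxcl2 with and without induction, which is what that source predicts. For Cd74 it gave 76.0% and 181.2%, the latter above the whole difference, so that gene stays open. For Fcer1g it gave up to 51.8%, which leaves it open beside the Ptprc segment, and for the other genes higher in STING-expressing cells at most 23.3%, which argues against it as their main source. Fcer1g is also in the NK marker set. The unnamed kept cluster led by NK receptor genes held 142 and 83 STING-expressing but 14 and 10 STING-deficient cells with and without induction. That cluster was not weighed as a source of the Fcer1g difference and stays open too. STING itself stays open, untested, for genes such as Slc15a2, Mid1, Rab4a and Lrmp. Other inherited differences between the OT-I cells of the genotypes were not tested either and cannot be told apart from STING here. CD8 T cells other than the transferred ones among the kept cells were not tested for and stay open as well.

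Cadps2, Fnbp1l and Ppp2r3a were counted mainly without induction, in both genotypes. A single source of reads assigned to several loci may lie behind the first 2 genes: the Cadps2 to Fnbp1l UMI ratio was 4.604 and 4.893 in the uninduced libraries, a quotient of 1.063, and 18 of 18 cluster intervals held their library's ratio. For Ppp2r3a this stays open, since its ratio to Cadps2 gave a quotient of 1.259 and 15 of 18 intervals held it. Across cells of these libraries, which are not replicates, Cadps2 had r of 0.537 and 0.606 with Fnbp1l and of 0.436 and 0.571 with Ppp2r3a. Each library's ratio includes the same clusters whose intervals were asked to hold it. Genes expressed together in the same cells could also give a steady ratio and such r. These values therefore do not tell a single source of reads from shared expression. For Cadps2, free RNA taken up by all cells alike is argued against by a 5.793-fold range of CPM over clusters. A shift in the mix of clusters is argued against by a highest within-cluster ratio of 0.1166 with over without induction, computed with 1 CPM added to both levels. What the source is, and why it goes with the uninduced libraries, was not tested, nor was any biological explanation.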
